A study of Mus musculus with 10 samples.

How the data were processed

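Poly-A RNA of 10 libraries of mouse hepatic stellate cells was sequenced, 5 from control cultures and 5 from cultures with recombinant Areg. Per the labels' protocols, libraries were made with a TruSeq kit after poly-A selection. The deposited files hold kallisto's estimated counts per transcript, which are expected counts that need not be whole, for 118489 transcripts in each library. The deposited files also hold TPM per transcript, which are scaled by the authors' kallisto run to transcript length and to the same total in each library, together with transcript and effective lengths in bases, per the file headers. The submitters' processing notes name kallisto 0.44.0, bcl2fastq 2.19, DESeq2 and the genome build GRCm38.p6, with no role or order. The transcript set and the strand setting of the counting are not given in the sources used here. kallisto shares reads between similar transcripts by estimation, so values of genes with near-identical paralogs or pseudogenes are uncertain, as are those of overlapping and antisense genes.

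Transcripts were joined to genes through the GENCODE M21 annotation of GRCm38, which also gave the coordinates. It matched 116816 transcripts, and the 1673 others held 0.736 to 0.778% of the estimated counts and entered no main test. Estimated counts were summed per gene, giving 36047 genes, and rounded to whole numbers. Total estimated counts were 17566891, 14878428, 10125184, 10950603 and 14481953 in controls 1 to 5 and 17994114, 19864632, 20057962, 14365027 and 18505132 in Areg libraries 1 to 5. Replicate pairs of a group differed by more than counting noise (chi-square per degree of freedom 3.775 to 50.7), so no library was taken as deposited more than once.

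Groups were taken from the labels. The Areg group was compared with the control group by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust estimation) with TMM factors and no covariates. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13362. The p-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05. Fold changes are Areg minus control on the log2 scale, and the SE was derived from the fold change and its F statistic. The biological coefficient of variation was 9.37%. CPM values are TMM-scaled.

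A total of 41 gene lists, covering signalling, matrix, stellate cell state, inflammation, metabolism, growth and markers of other liver cells, was fixed before the data were examined. The 39 lists with at least 5 tested members were tested with camera (limma 3.58.1, two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over lists), with camera at an estimated correlation and with fry. Library measures, 13 in all, were compared by two-sided exact permutation tests over all arrangements of the 10 libraries with Benjamini-Hochberg adjustment. Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes and pseudogenes and marking multigene families as uncertain. It also took up to 4 tested members of each list with the smallest p, and a panel of 8 genes. Bmf, Sesn3, Ulk1, Pink1, Fbxo32, Klf15, Cited2, Sparc, Fn1, Lamc1 and Grip2 were chosen after their values were seen. The values of 1 of the genes that the rule picks are not reported here.

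The test was checked on simulated data made from the means and library sizes of the Areg and control libraries, with 200 of 13362 genes changed in each of 5 runs. It recovered 37.0% of genes changed 1.25-fold, 70.7% of those changed 1.5-fold and 88.5% of those changed 2-fold, with 5.82% false calls. A list raised 1.2-fold was called in 5 of 5 runs and 0 of 100 untouched lists were called. The simulated genes varied independently, so this check does not cover false calls of lists whose members move together. The estimated correlation of the interferon list, for example, was 0.71. Changes of 1.25-fold were therefore often missed in the simulated data. The real test called 2226 genes, far more than were changed per run, so its recovery may differ.

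The alternatives were other normalization factors (DESeq2's size factors, upper quartile), other filters, DESeq2 1.42.0, limma-voom, the likelihood-ratio test, a transcript length offset, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), protein-coding genes alone, no mitochondrial genes, the replicate number as a block, 1 surrogate variable (sva 3.50.0) and each library left out. Leaving out controls 3 and 4, leaving out the genes that move with Grip2, removing a per-library trend in length and GC content, and adding the unmatched transcripts were chosen after the data had been seen.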

Results

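Poly-A RNA was sequenced from mouse hepatic stellate cells, the vitamin A-storing perisinusoidal cells of the liver that can become matrix-producing myofibroblasts. The labels describe quiescent cells of male C57BL/6 mice that were cultured for 5 h and then kept for 4 h in starving medium with recombinant mouse amphiregulin (Areg, 500 ng/mL) or without it. Areg is a ligand of the epidermal growth factor receptor (EGFR). Each group had 5 libraries, numbered 1 to 5. The libraries held 10125184 to 20057962 estimated counts, with a mean of 13600612 ± 3051315 in the control group and 18157373 ± 2294365 in the Areg group (SD, n = 5 each). The labels do not say whether the libraries came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. The design implies a single comparison, which asks how the transcriptome of these cells differed after 4 h with Areg. The series title places this question in work on amphiregulin from regulatory T cells in fatty liver disease.

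Areg-treated cells held more transcripts of the cytokine genes Il6 and Lif, of Inhba, of the EGFR ligand genes Areg and Ereg and of Dusp5 and Errfi1, whose products restrain EGFR signalling, and fewer of Lrat and Cygb, which mark quiescent stellate cells. Il6, which encodes interleukin-6, rose 1.97-fold from 46.6 ± 5.26 to 92.0 ± 7.23 CPM (TMM-scaled; mean ± SD, n = 5 in each group, as for all CPM pairs below). Inhba, the activin A subunit, rose 1.92-fold from 754 ± 90.6 to 1449 ± 89.0 CPM. Areg itself rose 2.02-fold from 12.4 ± 1.64 to 25.1 ± 2.59 CPM. Lrat, the enzyme that esterifies retinol for storage, fell from 44.9 ± 4.56 to 32.4 ± 1.17 CPM, a log2 fold change of -0.47.

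Of 13362 genes tested, 2226 (16.7%) differed between the groups at an edgeR adjusted p under 0.05, 1114 of them higher and 1112 lower with Areg. Most changes were small, and the median absolute log2 fold change of these genes was 0.28. A change of at least 2-fold was found for 38 genes, 26 higher and 12 lower, and a change of at least 1.5-fold for 93 higher and 71 lower genes. All 5 Areg libraries lay on one side of all 5 control libraries for 1964 genes (14.7%), where chance gives 0.794%. Controls 3 and 4 stood apart from the other libraries on the first principal component, at 46.6 and 28.6 against -16.5 to 0.455, and without both, an alternative added after the data had been seen, 2178 genes differed, 1147 higher and 1031 lower. The count was 1149 with a correction for transcript length and 856 on a log2(TPM + 1) scale, where 37.6% of the called genes were higher against 50.04% in the main test. Without Areg replicate 2 it was 1364.

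**Figure D1:**
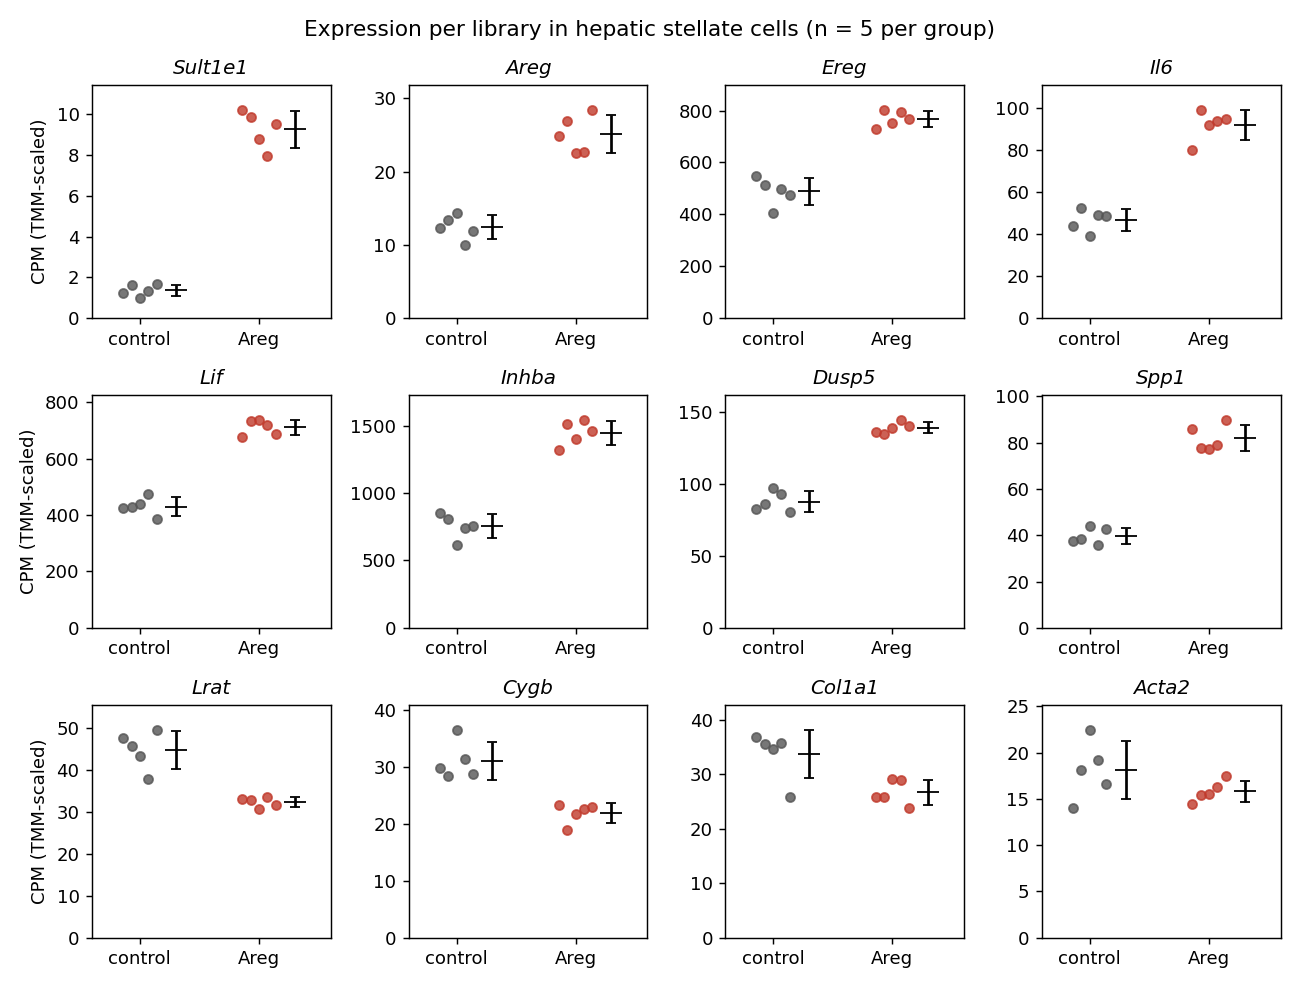
TMM-scaled CPM (vertical axes, starting at 0) of 12 genes in the 5 control libraries (grey) and the 5 Areg libraries (red), with the mean and SD of each group in black. The Areg libraries lie above every control library for Sult1e1, Areg, Ereg, Il6, Lif, Inhba, Dusp5 and Spp1 and below every control library for Lrat and Cygb, whereas the groups overlap for Col1a1 and Acta2.

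The genes that rose most belonged to several functions. Sult1e1, the estrogen sulfotransferase (chromosome 5, 87575969 to 87591594, GRCm38), rose 6.70-fold from 1.36 ± 0.270 to 9.28 ± 0.904 CPM (log2 fold change 2.75, SE 0.14, edgeR adjusted p = 4.72e-09). Sdr42e1, a short-chain dehydrogenase family member, rose 2.77-fold to 30.6 ± 3.15 CPM. Ch25h, which makes 25-hydroxycholesterol, rose 2.23-fold to 22.6 ± 4.43 CPM. Spp1, which encodes the matrix protein and cytokine osteopontin (chromosome 5, 104435118 to 104441050), rose 2.07-fold to 81.9 ± 5.63 CPM. Ccn2, the connective tissue growth factor gene, rose 2.01-fold from 182 ± 29.7 to 366 ± 62.5 CPM, with control 4 at 234 CPM and the other controls at 161 to 178 CPM. The chromatin protein gene Hmga2, the lubricin gene Prg4, the cornified envelope gene Sprr1a, the G-protein regulator Rgs16, the stromelysin Mmp10 and the potassium channel Kcnk10 rose between 2.00-fold and 2.46-fold. The edgeR adjusted p of these 12 genes, Areg included, was at most 0.00310.

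The genes that fell most were expressed at low levels. Depp1 (chromosome 6, 116650609 to 116652794) fell from 3.58 ± 1.34 to 1.06 ± 0.284 CPM (log2 fold change -1.70, SE 0.26, edgeR adjusted p = 0.000522). Nrg4, a neuregulin that binds ERBB4, fell from 2.30 ± 0.559 to 1.06 ± 0.186 CPM. Usp2, a deubiquitinase, fell from 7.62 ± 2.52 to 3.54 ± 0.436 CPM, and Cox6b2, a cytochrome oxidase subunit, from 6.12 ± 1.46 to 2.81 ± 0.538 CPM. Icosl, which encodes a ligand of the T cell costimulator ICOS, fell from 14.1 ± 2.22 to 7.86 ± 0.701 CPM. Ahnak2, Lrrc20, the adenosine receptor Adora1, Zfp13 and Cercam had log2 fold changes from -0.97 to -0.84. Gls2, a glutaminase, had a log2 fold change of -0.86 and an edgeR adjusted p of 0.0462, with control 3 at 10.04 CPM and the other controls at 3.50 to 4.14 CPM. Srp54b (log2 fold change -1.43) had 37.9 CPM in control 3 and 9.29 to 20.5 CPM in the other controls, and is uncertain because near-identical paralogs share its sequence. The fall of Gls2 was lost under 17 and that of Srp54b under 7 of 30 alternatives. Those of Cercam and Zfp13 were lost under 4 each, that of Adora1 under 3, and those of Nrg4 and Usp2 under 1 each.

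Of the 41 gene lists fixed before the data were examined, 39 had at least 5 tested members, and camera called 10 of them higher and 4 lower. No list was called with an estimated inter-gene correlation, where the lowest adjusted p was 0.0612, although 4200 genes had an unadjusted edgeR p under 0.05 and fry, which asks whether a list's genes move one way, called 14 lists. The lists called by fry differed from those called by camera in that chemokines and interferon-stimulated genes were left out (fry adjusted p = 0.118 and 0.317) and secreted growth factors and the unfolded protein response were added (fry adjusted p = 0.0166 and 0.0242). Regroupings of the same 10 libraries gave camera calls for a median of 6 lists, against 14 for the real groups. Without controls 3 and 4, camera called 22 lists, and 2 of them, cytokines and feedback regulators, also with an estimated correlation.

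Cytokine genes were higher with Areg. Of 19 tested, 9 rose, 1 fell and 9 did not pass the gene test; the counts were 9 and 1 adjusted over the list alone. The list was called by camera (adjusted p = 1.55e-08) but had an adjusted p = 0.0612 with an estimated correlation. Lif, the leukemia inhibitory factor gene, rose from 431 ± 32.3 to 712 ± 26.9 CPM, and Il11, a cytokine gene linked to fibroblast activation, from 392.4 ± 37.0 to 558 ± 18.8 CPM. Il1b rose from 20.1 ± 2.34 to 30.9 ± 3.35 CPM. Il6 (chromosome 5, 30013114 to 30019981) had a log2 fold change of 0.98 (SE 0.08, edgeR adjusted p = 5.85e-07).

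Feedback regulators of ERK and EGFR signalling rose as a list, with 11 of 26 tested members higher, 1 lower and 14 not passing, and 11 and 1 adjusted over the list alone. The camera adjusted p was 4.14e-06, and the adjusted p was 0.0612 with an estimated correlation. Dusp5, a nuclear ERK phosphatase, rose from 87.8 ± 7.08 to 139 ± 3.90 CPM. Errfi1, whose product inhibits the EGFR kinase, rose from 191 ± 16.2 to 298 ± 15.4 CPM. Socs3 and Spry4 rose by log2 0.52 and 0.38. Among 25 immediate-early transcription factors, 5 rose and 2 fell (6 and 3 adjusted over the list alone), including Egr1 (log2 fold change 0.37), Egr2 (0.69) and Egr3 (0.93), and the list was not called (camera adjusted p = 0.0739). That list was called under 8 alternatives, among them without control 3, without control 4 and without Areg replicate 5, and without controls 3 and 4 together its camera adjusted p was 8.01e-06, and the adjusted p was 0.117 with an estimated correlation.

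Genes of the EGF receptor family and its ligands moved in both directions. Of 12 tested genes of the EGF receptor family and its ligands, 5 rose, 3 fell and 4 did not pass (6 and 3 adjusted over the list alone; camera adjusted p = 0.00302, and adjusted p = 0.116 with an estimated correlation). Ereg, the epiregulin gene (chromosome 5, 91074622 to 91093646), rose from 488 ± 53.2 to 769 ± 30.9 CPM. Areg (chromosome 5, 91139599 to 91148432) and Btc, the betacellulin gene (chromosome 5, 91357261 to 91402994), lie nearby on the same chromosome and rose by log2 1.02 and 0.76. Another ligand gene of the list that lies nearby did not pass. Hbegf rose by log2 0.39 and Egfr from 249 ± 17.1 to 284 ± 8.72 CPM (edgeR adjusted p = 0.0173), a call that was lost under 6 of the 30 alternatives. The ligand gene Nrg4 fell, as did receptor genes of the list other than Egfr.

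Ribosome biogenesis genes were higher, with 13 of 28 tested genes up, 0 down and 15 not passing (17 and 0 adjusted over the list alone; camera adjusted p = 3.27e-08, and adjusted p = 0.110 with an estimated correlation). The examples were Dkc1 (log2 fold change 0.41), Npm1 (0.40), Wdr43 (0.31) and Ddx21 (0.28), which encode nucleolar proteins; Npm1 has processed pseudogenes that can share its reads. Among 28 cytosolic ribosomal protein genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), and that list was not called (camera adjusted p = 0.135), but was called under 6 alternatives, among them without control 3 and without controls 3 and 4 together (camera adjusted p = 0.000461, and adjusted p = 0.657 with an estimated correlation).

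Cytoskeletal genes rose without a rise in smooth muscle actin. In the contractile and myofibroblast list 11 of 21 tested genes rose, 1 fell and 9 did not pass (13 and 1 adjusted over the list alone; camera adjusted p = 0.000405, and adjusted p = 0.110 with an estimated correlation). The members with the smallest p were Tagln2 (log2 fold change 0.28), Cnn2 (0.39), Cnn3 (0.22) and Vcl (0.21), which encode actin-binding or adhesion proteins. The rises of Vcl and Cnn2 were lost under 4 and 3 of the 30 alternatives, with log2 fold changes of 0.10 to 0.13 and 0.26 to 0.30 there. Acta2, the smooth muscle actin gene and usual myofibroblast marker, had 18.1 ± 3.13 CPM in controls and 15.8 ± 1.14 CPM with Areg (edgeR adjusted p = 0.245). Vascular smooth muscle and pericyte markers together took a larger share of counts with Areg before adjustment (exact permutation p = 0.0397, adjusted p = 0.103). Gene by gene these markers did not rise. Of 8 tested, 1 was higher, 1 was lower and 6 did not pass, with a median of -0.08 (camera adjusted p = 0.697). In the list of YAP and TEAD targets 5 of 21 genes rose, 2 fell and 14 did not pass (5 and 4 adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.192 with an estimated correlation). F3, the tissue factor gene, rose from 30.0 ± 1.19 to 51.1 ± 1.76 CPM, Ankrd1 by log2 0.83, Ccn1 by 0.68 and Ccn2 by 1.00. That call ended without control 2, without control 5 and without the genes shared with other lists.

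Quiescence markers and retinoid genes were lower. Of 27 tested quiescent stellate cell markers, 11 fell, 1 rose and 15 did not pass (13 and 1 adjusted over the list alone; camera adjusted p = 0.000437, and adjusted p = 0.0612 with an estimated correlation). Cygb, the globin gene cytoglobin, fell from 31.03 ± 3.29 to 21.9 ± 1.74 CPM and Prelp from 300.4 ± 23.6 to 243 ± 7.25 CPM, while Nes, the nestin gene, rose by log2 0.33. Of 26 retinoid metabolism genes, 11 fell, 2 rose and 13 did not pass (12 and 3 adjusted over the list alone; camera adjusted p = 0.00132, and adjusted p = 0.117 with an estimated correlation). Lrat (chromosome 3, 82892579 to 82903973, edgeR adjusted p = 0.000293), Rxra, Dhrs3 and Pnpla2 had log2 fold changes of -0.47, -0.35, -0.34 and -0.37. The retinoid call ended without the genes shared with other lists.

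Collagen genes were lower in the main test, and this depended on the correction used. Of 19 tested, 7 fell, 0 rose and 12 did not pass (9 and 0 adjusted over the list alone; camera adjusted p = 0.000405, and adjusted p = 0.394 with an estimated correlation). Col1a2 fell from 84.8 ± 7.08 to 66.9 ± 3.82 CPM, and Col6a2, Col6a3 and Col5a1 had log2 fold changes of -0.31, -0.31 and -0.26. The calls of Col6a3, Col6a2 and Col5a1 were lost under 4, 2 and 2 of the 30 alternatives, with log2 fold changes between -0.17 and -0.06 there. Col1a1 went from 33.7 ± 4.48 to 26.7 ± 2.28 CPM (log2 fold change -0.34, edgeR adjusted p = 0.0167), with control 5 at 25.8 CPM and the other controls at 34.6 to 36.8 CPM, a call that was lost under 8 of the 30 alternatives. With a per-library trend in transcript length and GC content removed, an alternative chosen after the data had been seen, the list median moved from -0.18 to -0.01 and the camera adjusted p to 0.110, whereas with the trend removed and controls 3 and 4 also left out the median was -0.12 and the list stayed called (camera adjusted p = 0.00398). Other matrix genes moved in both directions. In the list of matrix glycoproteins and proteoglycans 5 of 30 rose and 4 fell (5 and 5 adjusted over the list alone; median -0.04, camera adjusted p = 0.499), with Thbs1 up from 659 ± 64.2 to 994 ± 82.9 CPM, Tnc up 1.36-fold and Has1 up 1.68-fold. Those that fell, as the collagens did, were Prelp, Sparc (log2 fold change -0.26), the fibronectin gene Fn1 (-0.19) and the laminin gene Lamc1 (-0.17, lost under 7 of the 30 alternatives), of which Sparc, Fn1 and Lamc1 were chosen after their values were seen. Among 32 proteases and inhibitors of matrix turnover 8 rose and 5 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.124), including rises of Mmp3 by log2 0.65 and Mmp13 by 0.37; that list was called under 7 alternatives, among them without control 4 or Areg 1 and without controls 3 and 4 together (camera adjusted p = 0.0125, and adjusted p = 0.546 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose from 33.0 ± 3.98 to 40.1 ± 3.30 CPM (edgeR adjusted p = 0.0217), but the groups overlapped and the call was lost under 5 of the 30 alternatives. Tgfb1 had a log2 fold change of -0.12 that did not pass (edgeR adjusted p = 0.375), with 353 and 336 CPM in controls 3 and 4 and 249 to 278 CPM in the other controls, and without controls 3 and 4 its log2 fold change was 0.05. With the trend removed Tgfb1 was called higher, at 0.12 (edgeR adjusted p = 0.0485), and at 0.16 without controls 3 and 4 as well (edgeR adjusted p = 0.00533).

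Chemokine and interferon-stimulated genes gave list calls that were lost with an estimated correlation and with fry. Of 18 chemokine genes 7 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00338, and adjusted p = 0.691 with an estimated correlation). Cxcl1, a neutrophil attractant, rose 1.48-fold and Ccl7 from 240 ± 24.7 to 301 ± 19.9 CPM. Of 25 interferon-stimulated genes 3 rose, Ddx58, Ifih1 and Irf9, and 22 did not pass (3 adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.744 with an estimated correlation), a list call that also ended without control 1, control 2, Areg 3 or Areg 4. The rises of Ddx58, Ifih1 and Irf9 were lost under 6, 5 and 5 of the 30 alternatives. In the list of NF-kappaB and acute inflammatory genes 4 of 26 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.135), among them the prostaglandin synthesis genes Ptgs2, from 230 ± 18.9 to 344 ± 15.3 CPM, and Ptges, from 48.6 ± 2.84 to 66.9 ± 2.07 CPM. That list was called under 8 alternatives, among them without control 3, control 4 or Areg 5 and without controls 3 and 4 together (camera adjusted p = 0.00162, and adjusted p = 0.546 with an estimated correlation). The rise of Ptges was lost under 4 of the 30 alternatives, with log2 fold changes of 0.22 to 0.26 there against 0.46 in the main test. Glycolysis and hypoxia-inducible genes were lower, 9 of 25 with 0 higher (10 and 2 adjusted over the list alone; camera adjusted p = 0.00199, and adjusted p = 0.259 with an estimated correlation), with Slc16a3, Bnip3, Pfkfb4 and Pfkl at log2 fold changes of -0.44, -0.40, -0.39 and -0.28; that call ended with the length and GC trend removed, where the median moved from -0.11 to -0.08 (camera adjusted p = 0.0651), but not with controls 3 and 4 also left out (median -0.08, camera adjusted p = 0.0142). The panel of 8 genes named in every case, which holds Areg, Il6 and Lrat, had 4 genes higher and 2 lower, likewise 4 and 2 adjusted over the list alone, and was called higher (camera adjusted p = 0.0261, and adjusted p = 0.118 with an estimated correlation), but not without control 1 or control 5.

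**Figure D2:**
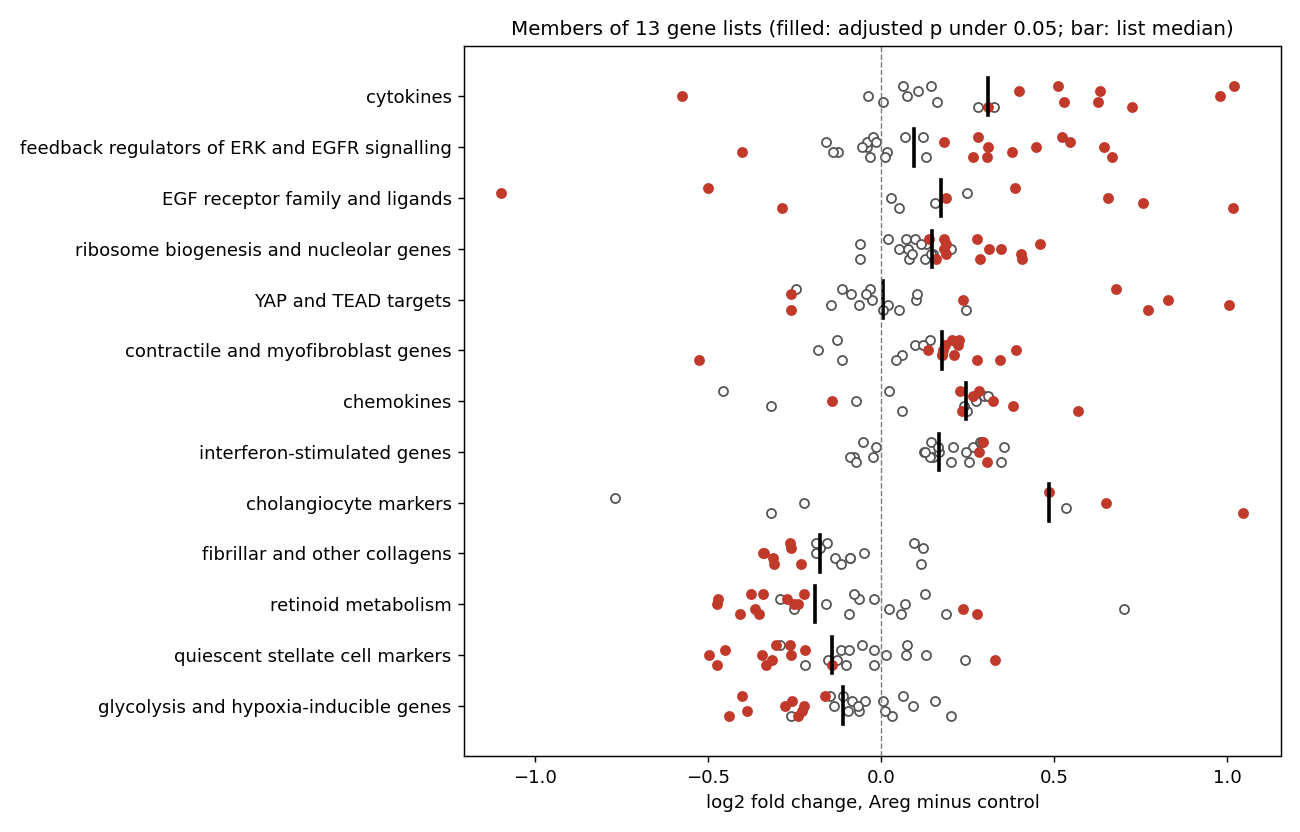
Log2 fold change, Areg minus control (horizontal axis), of each tested member of 13 gene lists, with filled points at an edgeR adjusted p under 0.05, open points above it and a bar at each list median. The cytokine median lies at 0.31 and the collagen median at -0.18.

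Transcripts of other liver cells were present in both groups. Endothelial markers took 0.887 ± 0.0307% of counts in controls and 0.849 ± 0.00416% with Areg (exact permutation p = 0.0476, adjusted p = 0.103 over 13 library measures), and hepatocyte markers 0.379 ± 0.0561% and 0.392 ± 0.0361%. The hepatocyte list was not called, but it was called higher under 5 alternatives, among them without control 3, without Areg 5 and without controls 3 and 4 together, with a median of 0.22 (camera adjusted p = 0.000232, and adjusted p = 0.546 with an estimated correlation). Kupffer cell and macrophage markers took 0.183 ± 0.00706% and 0.163 ± 0.00623%, lower in all 5 Areg libraries (exact permutation p = 0.00794, the smallest that the permutations allow, adjusted p = 0.0516). Slc40a1, the iron exporter gene of that list, fell from 730.0 ± 73.2 to 542 ± 52.5 CPM, which makes up most of the fall in that share, while its list was not called (2 of 20 genes higher and 2 lower, likewise adjusted over the list alone; camera adjusted p = 0.697). Cholangiocyte markers took 0.0185 ± 0.00157% and 0.0288 ± 0.00247% (exact permutation p = 0.00794, adjusted p = 0.0516), and 3 of the 7 tested genes rose (4 adjusted over the list alone), Spp1, Krt18 (log2 fold change 0.65) and Krt8 (0.49), the keratins also being expressed by hepatocytes and having pseudogenes that can share their reads. That list was called higher (camera adjusted p = 7.72e-05, and adjusted p = 0.0797 with an estimated correlation), and the call ended without the genes shared with other lists. Total estimated counts, the mitochondrial share, 2.88 ± 0.155% against 3.28 ± 0.279%, and vascular smooth muscle and pericyte markers, 0.0757 ± 0.00359% against 0.0811 ± 0.00237%, were also higher with Areg before adjustment (exact permutation p = 0.0397 for each, adjusted p = 0.103). The tests of library measures were two-sided. With 13 measures, 2 at the smallest possible p reach an adjusted p of 0.0516 at best. The Kupffer and cholangiocyte shares alone therefore could not pass, whatever the size of their difference. They passed without control 1 and without control 5 (adjusted p = 0.0344) at the same exact permutation p = 0.00794. Another share also reached that p there, the smooth muscle share without control 1 and the endothelial share without control 5. These passes are no added support.

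**Figure D3:**
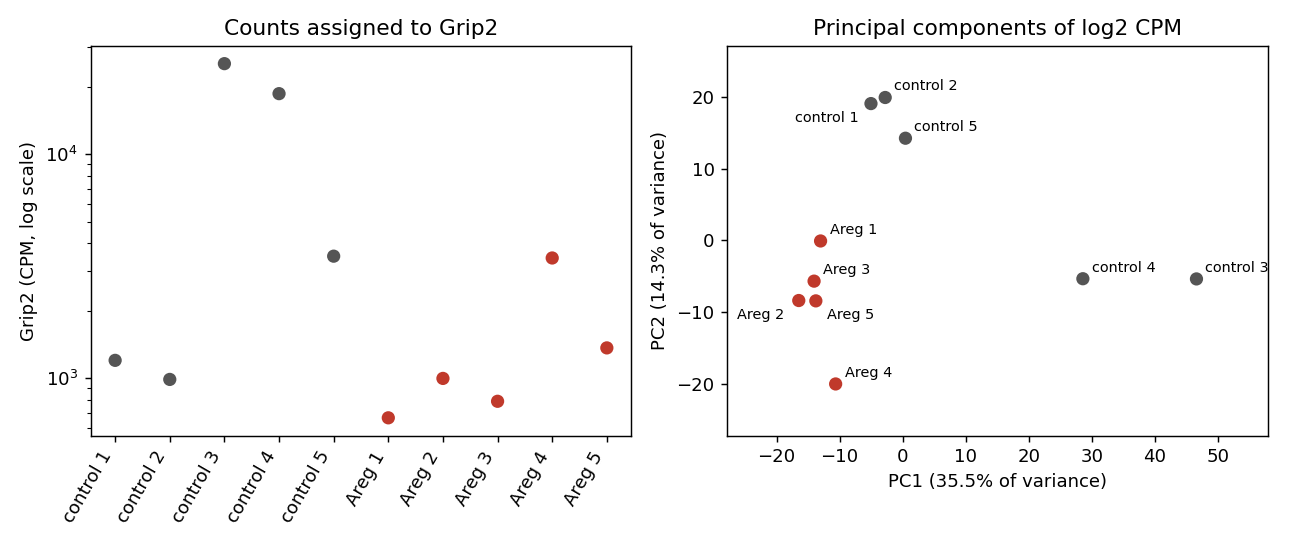
Left, TMM-scaled CPM assigned to Grip2 (log axis) in each of the 10 libraries; right, the first principal component (horizontal axis, 35.5% of the variance) and the second (vertical axis, 14.3%) of log2 CPM, controls in grey and Areg libraries in red. Controls 3 and 4 have 25353 and 18626 CPM of Grip2 and lie apart from the other 8 libraries on the first component.

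The other lists were not called in the main test. The camera adjusted p was 0.124 for secreted growth factors, 0.135 for the unfolded protein and integrated stress response, 0.147 for oxidative phosphorylation, 0.168 for antigen presentation, 0.392 for TGF-beta ligands, receptors and targets and for semaphorins, ephrins and migration receptors, and 0.528 for the insulin and IGF pathway. It was 0.499 for cholesterol biosynthesis, for fatty acid synthesis and lipid storage and for dissociation stress, 0.674 for cell-cycle inhibitors and p53 targets, 0.697 for G2/M genes, 0.704 for G1/S genes and 0.936 for the notch pathway. Among the marker lists it was 0.321 for hepatocytes, 0.605 for endothelial cells, 0.674 for portal fibroblasts and mesothelium, 0.697 for smooth muscle and pericytes and 0.704 for erythroid cells and platelets. The median and the mean differed in sign for the matrix glycoprotein, TGF-beta, cholesterol, p53 and hepatocyte lists, and the mean and the camera direction for the hepatocyte, smooth muscle and erythroid lists. Some of these lists were called under other settings: secreted growth factors and the unfolded protein response under 7 alternatives each and oxidative phosphorylation under 4, all including the tests without control 3 and without controls 3 and 4 together (adjusted p = 0.143, 0.384 and 0.657 there with an estimated correlation), TGF-beta genes and semaphorins under 2 with the length and GC trend removed, and antigen presentation without Areg 3. Lymphocyte markers and neutrophil and dendritic cell markers had 4 tested members each and were not tested as lists.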

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

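The tests of a shared source and of mitochondrial and 5S ribosomal RNA for Grip2, of controls 3 and 4 and of the share of stellate cells for the collagens, and of both explanations for the cholangiocyte markers, with the differences within libraries, were chosen only after the result was seen. An earlier form of the stellate cell test, on marker shares, argued against that explanation mainly through 1 gene, Slc40a1, and was replaced by list means.

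Of 242 groups of 5 values tested, 13 (5.37%) held a value whose gap to its neighbour, as a share of the group's range, exceeded Dixon's critical value of 0.71; chance gives about 1 in 20 such groups. Of these, 5 lay in control 3 or control 4. In control 4, Ccn2 had 234 CPM against 161 to 178 in the other controls (ratio 0.770) and Cnn2 had 35.8 against 26.2 to 28.2 CPM (0.793). In control 3, Cox6b2 had 8.64 against 5.15 to 6.13 CPM (0.717), Gls2 had 10.04 against 3.50 to 4.14 CPM (0.902) and Dgat1 had 53.6 against 38.4 to 42.0 CPM (0.765). In control 1, Ccl7 had 198 against 241 to 258 CPM (0.729), Krt18 had 43.0 against 53.3 to 54.7 CPM (0.880), Lamc1 had 964 against 835 to 867 CPM (0.75) and the cholangiocyte markers took 0.0158% against 0.0187 to 0.0198% of counts (0.731). In control 5, Col1a1 had 25.8 against 34.6 to 36.8 CPM (0.807). Among Areg libraries, Cnn2 had 40.9 against 37.1 to 37.8 CPM in Areg 4 (0.828), and Ddx21 had 563 against 589 to 599 CPM in Areg 1 (0.723). Among the transcripts that matched no annotated gene, which entered no main test, 29 of 416 tested were higher and 20 lower with Areg at an edgeR adjusted p under 0.05.

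Grip2, a glutamate receptor-binding protein gene (chromosome 6, 91761509 to 91827250, GRCm38), had 25353 and 18626 CPM in controls 3 and 4, 3504 in control 5, 987 to 1201 in controls 1 and 2, and 3439 in Areg 4 against 665 to 1365 in the other Areg libraries (Dixon ratio 0.748); the difference between the groups did not pass (edgeR adjusted p = 0.116). With 18 genes that moved with it, it took 2.66% and 1.95% of counts in controls 3 and 4 and 0.0719 to 0.371% elsewhere. The most abundant transcript of each of these 19 genes was compared with annotated ribosomal RNA. Of the 19, 0% shared a 31-base stretch with mitochondrial or 5S ribosomal RNA. Likewise 0% shared one with 4 annotated transcripts that hold nuclear ribosomal RNA. This argues against these annotated sequences as sources. The nuclear set held only 6952 bases, so nuclear ribosomal RNA outside it was not tested. Reads of 1 shared source may still be spread over these genes. The ratio of each gene to Grip2 varied between libraries by a median of 26.5%, between the bounds of 25% and 50% set for and against a shared source. The genes were picked for following Grip2 in these same libraries, which favours a steady ratio, so a shared source stays open. Both high libraries are controls, and no biological explanation was tested.

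The fall of the collagen genes depended on the correction. With a trend in length and GC content removed per library, the list median moved from -0.18 (quartiles -0.26 and -0.09) to -0.011 (-0.12 and 0.04), and the camera adjusted p became 0.110, because the fold changes themselves shrank; such a trend is a candidate explanation. Against it, with the trend removed and controls 3 and 4 also left out, the median was -0.12 (quartiles -0.17 and 0.02), 4 genes were lower and the list stayed called (camera adjusted p = 0.00398); since those quartiles span 0, this does not exclude the trend, which stays open. Without controls 3 and 4 alone the median was -0.22 (camera adjusted p = 2.34e-06, and adjusted p = 0.324 with an estimated correlation, against 0.394 with all libraries), which argues against those libraries as the cause. Fewer stellate cells among the Areg cultures cannot be told apart from a change within them, since the mean log2 fold changes of endothelial (-0.025), Kupffer (-0.03) and hepatocyte markers (-0.01) lay within 2 SE of 0. That SE was taken over the genes of each list and not over libraries. An effect of Areg on collagen transcripts also stays open.

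The cholangiocyte list rose through Spp1, Krt8 and Krt18, whose summed counts rose by log2 0.67 (95% interval 0.48 to 0.87). Cholangiocytes would bring their other transcripts too, but the 12 other members together had a log2 fold of -0.04 with an upper 95% limit of 0.38, from 1153 counts; within libraries the sums differed by 0.71 (0.26 to 1.16), and by 0.71 (0.09 to 1.33) without controls 3 and 4, although for the keratins alone that interval then held 0 (lower limit -0.06). Hepatocyte markers, whose cells hold both keratins, had a log2 fold of 0.07 with an upper limit of 0.35, below the 0.49 of Krt8, and without controls 3 and 4 a fold of 0.21 with an upper limit of 0.46; Krt8 exceeded them within libraries by 0.41 (0.29 to 0.53) and by 0.36 (0.26 to 0.45). These values argue against cholangiocytes as the source of the summed rise and against hepatocyte RNA as the whole source of the rise of Krt8, while hepatocyte RNA may account for part of it and cholangiocytes for part of the keratins. Other cell types and reads shared with keratin pseudogenes were not tested, so a response of the stellate cells is left as a hypothesis beside them.

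Other groupings of the 10 libraries did not give the gene counts: in 100 of the 126 possible splits, the real groups gave 2226 genes, and 1 split, the real one, gave as many, the highest other giving 2. For changes of at least 2-fold the real count was 38, again reached by 1 split, and the highest other was 1. The other splits mix Areg and control libraries, so any difference between the groups adds to their spread and lowers their counts. A chance difference between animals or cultures is not excluded, since the labels do not say whether the libraries came from separate ones. For the number of lists called by camera, the splits cannot decide, and chance stays open. As many as the real 14 were called by 5 of 100 splits, the real one included, and the highest other called 19. That met the bound set for chance before the result was seen, which was 5% of the splits or more. The others among these 5 each put 1 Areg library with controls 1, 2, 4 and 5. They thus held most of the real difference and are no reference for chance. By list, the real split alone gave so small a camera p for cytokines, feedback regulators, EGF receptor ligands, ribosome biogenesis, quiescence markers, YAP and TEAD targets, cholangiocyte markers and the panel of 8 genes, whereas 3 splits did for retinoid genes, 5 for contractile genes, 6 for glycolysis, 12 for collagens, 30 for chemokines and 68 for interferon-stimulated genes. The counts per list were looked at only after the result was seen.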

How the results depend on the processing

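Leaving out controls 3 and 4, removing the length and GC trend, leaving out the genes that move with Grip2 and adding unmatched transcripts were chosen after the result was seen; the others were planned. Of 108 named genes, 105 were called, all 105 kept their direction under all 30 alternatives, and 73 stayed past the threshold under each. Most were picked for their values in these same libraries, so kept directions are no independent support. Gls2 was lost under 17, Klf15 under 14, Col1a1, Fbxo32 and Pink1 under 8 each, Srp54b and Lamc1 under 7 each, Ddx58 and Egfr under 6 each, and Ifih1, Irf9 and Timp1 under 5 each. Cercam, Col6a3, Pfkfb4, Ptges, Rxra, Sesn3, Vcl and Zfp13 were lost under 4 each, and Adora1 and Cnn2 under 3 each. The count of 2226 genes (1114 higher, 1112 lower) was 1149 (617 and 532) with a transcript length offset, 856 (322 and 534, 14 of at least 2-fold) on log2(TPM + 1) and 868 (325 and 543) on log2(TPM + 0.1), where 37.6% and 37.4% of called genes were higher against 50.04%; the cause was not tested. The other tools and scalings gave 1985 (no count filter) to 2593 genes (DESeq2), with 44.0% higher under upper-quartile factors and 58.3% with no filter. Leaving out 1 library gave 1364 to 2314 genes, 686 to 1181 higher, 678 to 1150 lower and 30 to 50 of at least 2-fold. It gave 12 to 21 lists, and the cause of these ranges was not tested. It also gave 0 to 3 library measures at an adjusted p under 0.05, 3 without control 1 or control 5. As shares of TPM, 2 measures passed. The Kupffer and cholangiocyte shares had the same exact permutation p = 0.00794 in all these settings. Their adjusted p moved with how many measures were tested and how many reached that p. Without controls 3 and 4, 1643 of 2178 called genes were shared with the main test, and with the trend removed 1284 of 1921. The 14 lists became 22 with 1 surrogate variable, 22 without controls 3 and 4, 23 with the trend also removed, 0 with an estimated correlation and 2 with it and without controls 3 and 4; the cause was not tested. Tgfb1 turned from a log2 fold change of -0.12 to 0.026 with 1 surrogate variable, 0.054 without controls 3 and 4, 0.12 with the trend removed (edgeR adjusted p = 0.0485) and 0.16 with both (edgeR adjusted p = 0.00533); the cause was not tested. In the simulated data the genes with the smallest changes were missed most often.

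The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated across genes at 0.0548, 0.0912, -0.0465, 0.144 and 0.00334, and only numbers 2 and 4 correlated best with their own number. The replicate block gave 2357 genes and 14 lists, and 1097 genes (614 higher, 483 lower) with the length offset.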

Other observations

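The test of the FOXO targets was planned before its result was seen, but its starting genes and Bmf, Ulk1, Sesn3, Pink1, Fbxo32, Klf15 and Cited2 were chosen only after their values were seen.

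Secreted growth factor genes moved in both directions, with 7 of 31 tested genes higher and 5 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.124). Angptl4, an inhibitor of lipoprotein lipase, rose from 79.2 ± 7.38 to 118 ± 3.40 CPM. Fgf2 and the angiopoietin gene Angpt2 rose by log2 0.53 and 0.40, whereas Bmp6, an inducer of hepcidin, had a log2 fold change of -0.36. In the insulin and IGF list 2 of 24 genes rose and 3 fell (2 and 3 adjusted over the list alone), among them Irs2, an insulin receptor substrate, at -0.33 and the transcription factor gene Foxo3 at -0.38. Dgat1, the last enzyme of triglyceride synthesis, and the lipid droplet coat gene Plin2 had log2 fold changes of -0.41 and -0.24, in a lipid synthesis and storage list of 27 with 3 genes higher and 4 lower (3 and 4 adjusted over the list alone). The stress genes Hmox1, which encodes heme oxygenase, and Bag3 had log2 fold changes of -0.37 and -0.30 (edgeR adjusted p = 0.00209 and 0.000911), and their list had 4 of 21 genes higher and 4 lower (5 and 6 adjusted over the list alone). Stab1, an endothelial scavenger receptor gene, fell from 847 ± 62.7 to 691 ± 36.4 CPM. Mup20, a major urinary protein gene of hepatocytes, rose by log2 0.48 and is uncertain because it belongs to a multigene family.

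Depp1, Bmf, Irs2 and Foxo3, which are reported FOXO targets or a FOXO factor, fell, Bmf by 0.83 on the log2 scale. The hypothesis that FOXO targets may fall together was tested on 17 other targets from a list written before the test. Of these, 5 fell (Ulk1, Sesn3, Pink1, Fbxo32 and Klf15), 1 rose (Cited2, log2 fold change 0.41) and 11 did not pass, with a median of -0.07. Of the falls, those of Klf15, Pink1, Fbxo32 and Sesn3 were lost under 14, 8, 8 and 4 of the 30 alternatives. The camera p was 0.0792, and the p was 0.0953 with an estimated correlation, so the test did not bear the hypothesis out, although it does not show that these genes stayed the same.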
